A study of Mus musculus with 15 samples.

How the data were processed

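Per the file headers, the authors deposited 1 table per library with FPKM, its lower and upper bound at 95% confidence and an estimate status for each of 46966 genes. Per the submitters' processing notes, Bowtie 0.12.2, FastQC and genome build GRCm38.p2 were used, with roles not stated there, and the program that computed the FPKM was not named. The labels state that embryonic age was counted from the vaginal plug, that livers were flash frozen, that RNA was extracted with Trizol and that sequencing ran on an Illumina HiSeq instrument. Counts would have been tested with a count model. The tables hold FPKM only, so the test planned for normalized values was used. Proteome data named in the series description were not used here.

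The 15 libraries formed 3 periods of 7, 3 and 5 ages. The 2484 entries on scaffolds outside the chromosomes were left out, which left 44482 genes. For 1504 symbols an entry existed in both places, and reads may be split between them, so genes with such a copy were treated as uncertain. The 54 symbols repeated on chromosomes were left out of the gene lists. Of the values, 26 in 10 genes had a status of failed estimate and were set to missing: Alb, Hba-a1, Hba-a2, Hbb-bs, Hbb-bt, Rrbp1, Fetub, Cyp4f14, Cpt1a and Dak.

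Depth was estimated from the authors' bounds. For genes with 1 transcript, the upper bound equals the FPKM times 1 plus 2 over the root of the fragment number, so the number of fragments can be solved for. Of values solved to under 200 fragments, 23.7% lay within 0.02 of a whole number. Relative depth came from 1920 genes whole in at least 8 libraries, and the depth in fragments from genes with a single exon over 1000 bases in GENCODE M21 (164 to 216 genes per library). The floor is the FPKM of 3 fragments on 1000 bases. These depths are estimates, and fragments per gene could not be recovered for most genes, so no count test was run.

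Tests used limma-trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1) of genes over 1 FPKM in at least 3 libraries, with Benjamini-Hochberg adjustment within each comparison and a threshold of adjusted p under 0.05. The pseudocount of 1 understates the change of low genes. The period contrasts came from 1 fit to all 15 libraries with period as the factor. The embryonic slope came from the 7 embryonic libraries with the day as a number, and the slope of the weeks from the 5 libraries with log2 of the week as a number. Genes highest in the postnatal days passed both contrasts upward, and the birth step has no test. Errors are standard errors of the fit, and means are given with the SD over the ages of a period. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

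Gene lists, 42 with 561 symbols, were written from general knowledge before the data were examined, and 558 symbols were matched, 6 of them by an older symbol. Lists with 5 or more tested genes were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over lists. Camera left out genes with a failed estimate in any library of the comparison, such as Alb, Fetub and Cpt1a in the period contrasts. Its lists can thus be smaller than the counts of tested members given beside it. Lists overlap in some genes. For the birth step each list's median was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. Transcript GC content was taken from GENCODE M21 for 95.4% of the tested genes.

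Named genes followed a rule written before the data were examined. For each comparison it takes the 5 largest rises and the 5 largest falls past the threshold with a mean of at least 10 FPKM, leaving out predicted genes. From each list it takes up to 3 members past the threshold by size of change and the most abundant member. For the peak in the postnatal days it takes the 10 genes with the largest smaller change, of which 4 reached 10 FPKM, and for the birth step the 10 largest rises and falls among genes at 50 FPKM or more and list members. The text names a part of these, some are not reported here, and Xist, Ddx3y and Lcn2 were given as levels. The immunoglobulin count among the peak genes was chosen after the values were seen.

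The fits were tried on libraries with known changes in a self-test, drawn from a normal distribution with each gene's mean and spread on the log2 scale. Changed genes were not taken from those lowest in expression, so recovery among low genes was not measured. With a true log2 change of 1 in 100 genes, 62% were recovered for weeks against embryonic days, 40% for days against embryonic days and 34% for weeks against days, and with a change of 2 it was 95%, 85% and 91%. Of the calls, 9.2%, 3.8% and 7.4% were unchanged genes. For the embryonic slope 42% were recovered at 0.2 and 97% at 0.5 per day (3.5% of calls unchanged), and for the slope of the weeks 9% at 0.5 and 57% at 1 per doubling (2.9% of calls unchanged). Camera called 20 of 20 shifted lists and 2 of 200 unshifted lists of 15 genes. Genes were drawn independently of each other, so this does not test the preset correlation for lists whose genes vary together. The simulated noise was also independent between ages, and most genes were unchanged. The shares of unchanged genes among the calls are therefore not rates of false calls in the real libraries.

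The totals lack genes whose estimate had failed. Alternatives fixed before the data were examined were no filter, a filter on 5 libraries, a pseudocount of 0.1, totals without globins and Alas2 or without the 50 most abundant genes, quantile normalization, log2 depth as a covariate, other groups of ages, each library left out in turn and a size threshold. Chosen after seeing the data were scaling by the median ratio over 8782 genes, removal of each library's GC trend in 50 bins, and leaving out E13.5, E16.5 and W6, or E15.5 to E17.5, or W6 and W8.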

Results

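Whole livers of C57BL/6 mice, a common inbred laboratory strain, were sampled at 15 ages and their RNA was sequenced, with 1 library per age. The libraries fell into 3 periods: 7 embryonic days from E12.5 to E18.5, the postnatal days D1, D3 and D5, and 5 postnatal weeks from W1 to W8. No age had a replicate, so the ages of a period stood in for replicates. The spread within a period holds change with age as well as noise, and for each comparison of periods some other cut into runs of consecutive ages called as many genes or more, so the counts do not single out the periods. Whether a library came from 1 animal or from several was not given in the sources used here. The p-values measure only the spread between these libraries. Values were FPKM, which scale fragments by transcript length and library total. The estimated depth was 17.0 M fragments at E12.5, 15.7 M at E13.5 and 17.5 M at E14.5. It was 19.9 M at E15.5, 20.3 M at E16.5, 18.8 M at E17.5 and 18.0 M at E18.5. After birth it was 16.8 M at D1, 17.1 M at D3, and 17.2 M at D5. In the weeks it was 16.5 M at W1, 16.6 M at W2, 17.1 M at W3, 20.7 M at W6 and 17.3 M at W8. At these depths 3 fragments on a transcript of 1000 bases corresponded to between 0.145 FPKM (W6) and 0.191 FPKM (E13.5). This floor covers counting error only. Between 10061 genes (W6) and 12760 genes (D1) lay above 1 FPKM.

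Age ordered the libraries. The first principal component over 13704 genes held 67.1% of the variance and ran from -106.6 at E12.5 to 123.5 at W6 and 120.6 at W8. The second held 15.2%. Between adjacent ages, Pearson's r of log2(FPKM + 1) across genes, which are not independent replicates, was lowest between W3 and W6 (0.935) and highest between E14.5 and E15.5 (0.988). Among genes at 10 FPKM or more, 18.4% at least doubled or halved from W3 to W6, 12.9% from W2 to W3, 9.4% from W1 to W2, 8.2% each from E18.5 to D1 and from W6 to W8, and between 0.7% (D5 to W1) and 5.7% (E15.5 to E16.5) at the other steps. Globin genes and Alas2, the erythroid enzyme of heme synthesis, took 30.7% of the summed FPKM at E12.5, 26.1% at E18.5, 11.3% at D1 and 0.2% at W8. Transcripts of the mitochondrial genome took between 7.4% (E13.5) and 29.1% (W3). Estimates had failed for alpha globins from E13.5 to E17.5, and for Alb, an abundant plasma protein gene, at E18.5, D3, D5 and W1 to W3. The globin shares from E13.5 to E17.5 therefore lie too low, and the other shares at all these ages too high, by an unknown amount. Xist, the RNA of the inactive X chromosome, lay between 5.87 FPKM (E13.5) and 35.9 FPKM (E15.5) in the embryonic libraries and at 0.314 FPKM (D5) or less after birth. The Y-linked Ddx3y was at 0.0109, 0.0425 and 0.0433 FPKM at E15.5, E16.5 and E17.5, and at 1.21 FPKM or more at the other ages, so E12.5, E13.5, E14.5 and E18.5 held both Xist and a Y-linked RNA. Holding both argues against a single animal as the only source of RNA in those libraries. The sex of the animals was not given in the sources used here. By Xist, sex shifted together with birth, so it cannot be told apart from period in the comparisons with the embryonic days. At E13.5, E16.5 and W6 each gene's departure from the mean of the adjacent ages followed transcript GC content, with Spearman's rho across 13068 genes of 0.703, 0.633 and 0.451.

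**Figure D1:**
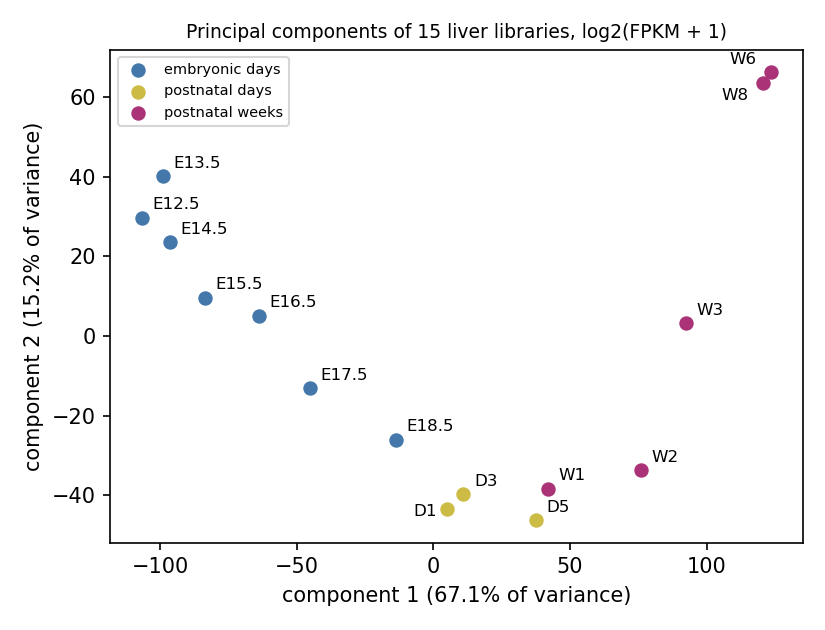
Scores of the 15 libraries on the first principal component (x axis, 67.1% of the variance) and the second (y axis, 15.2%), 1 point per library, coloured by period. The embryonic libraries lie from -106.6 to -13.8 on the x axis, the postnatal days from 4.8 to 37.5 and the postnatal weeks from 42.1 to 123.5.

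**Figure D2:**
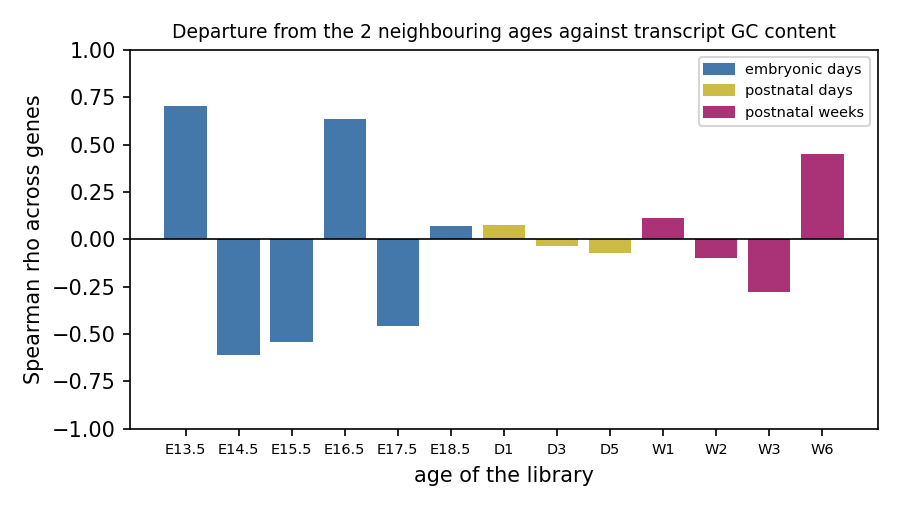
Spearman's rho across genes between transcript GC content and each library's departure from the mean of its adjacent ages (y axis), 1 bar per age with an age on each side (x axis), coloured by period. E13.5, E16.5 and W6 have 0.703, 0.633 and 0.451, and E14.5, E15.5 and E17.5 have -0.611, -0.541 and -0.459.

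The postnatal weeks were compared with the embryonic days to ask how the liver from W1 to W8 differs from that of the fetus. Cytochrome P450 genes rose in 22 of 23 tested and amino acid catabolism genes in 18 of 18, and erythroid genes fell in 19 of 19 and cell cycle genes in 23 of 23. With an estimated correlation these lists had adjusted p = 0.132, 0.177, 0.305 and 0.396 in that order. Cyp2e1, a cytochrome P450 that oxidises ethanol (GRCm38.p2 chromosome 7, 140763832 to 140774981, identifier gene18929), rose from 18.8 ± 31.4 FPKM (mean ± SD, n = 7 ages) to 1850 ± 591 FPKM (n = 5 ages), a log2 change of 7.36 ± 0.56 (SE; adjusted p = 3.2e-07). Pck1, the first committed enzyme of gluconeogenesis, changed by 7.34 ± 0.44 (adjusted p = 4.4e-08), and Cyp1a2 by 7.22 ± 0.48 (adjusted p = 1.1e-07). Slc4a1, the anion exchanger of the red cell membrane (chromosome 11, 102348820 to 102365281, identifier gene27518), fell from 948 ± 306 to 21.7 ± 40.3 FPKM, with a log2 change of -6.77 ± 0.66 (adjusted p = 1.1e-06). Mettl7b and Inmt, both methyltransferases, changed by 7.62 ± 0.32 and 6.88 ± 0.49. Of the other largest falls, Rhd, the Rh blood group protein, changed by -6.39 ± 0.60 and Cd24a, a surface protein of progenitors, by -6.36 ± 0.68.

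In the cytochrome P450 list, 22 of 23 (22 adjusted over the list alone) tested members rose (camera adjusted p = 3.3e-15, adjusted p = 0.132 with an estimated correlation), with a median 4.98 above that of all genes. Conjugating enzymes of phase II rose in 22 of 23 (22 adjusted over the list alone, with camera adjusted p = 3.3e-15, adjusted p = 0.102 with an estimated correlation), among them Ugt1a1, the bilirubin glucuronosyltransferase (5.46 ± 0.78). Amino acid catabolism rose in 18 of 18 (18 adjusted over the list alone, with camera adjusted p = 7.4e-13, adjusted p = 0.177 with an estimated correlation), led by the tyrosine and tryptophan enzymes Tat (6.87 ± 0.55) and Tdo2 (6.78 ± 0.60). All 10 tested members of the urea cycle list rose (10 adjusted over the list alone; camera adjusted p = 3.0e-07, adjusted p = 0.183 with an estimated correlation), among them Arg1, which releases urea (3.87 ± 0.95). Secreted proteins rose in 15 of 16 (15 adjusted over the list alone) for the plasma protein list (camera adjusted p = 1.4e-08, adjusted p = 0.245 with an estimated correlation). Complement genes rose in 17 of 18 (17 adjusted over the list alone, with camera adjusted p = 4.6e-11, adjusted p = 0.206 with an estimated correlation). Apoc3, an apolipoprotein of triglyceride-rich particles, changed by 6.58 ± 0.85, and Mbl2, a mannose-binding lectin, by 5.56 ± 0.68. Bile acid genes rose in 15 of 16 (15 adjusted over the list alone, with camera adjusted p = 1.5e-10, adjusted p = 0.177 with an estimated correlation), among them the uptake carrier Slco1b2 (5.12 ± 0.63). Of the hepatocyte transcription factors, 15 of 18 (15 adjusted over the list alone) rose (camera adjusted p = 3.4e-08, adjusted p = 0.177 with an estimated correlation), led by the xenobiotic receptor Nr1i3 (4.22 ± 0.54). Pericentral genes rose in 9 of 11 (10 adjusted over the list alone, with camera adjusted p = 2.3e-08, adjusted p = 0.0853 with an estimated correlation), and Cyp2e1 and Cyp1a2 stand in both that list and the P450 list.

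Erythroid, megakaryocyte, progenitor, neutrophil, cell cycle, oncofetal and imprinted growth lists moved the other way. The growth hormone and IGF list did not, with a median of 2.97. The B cell list had a median of -0.69 and the T and NK cell list of 0.07. All 19 tested erythroid genes fell (19 adjusted over the list alone; camera adjusted p = 1.5e-08, adjusted p = 0.305 with an estimated correlation), with a median of -4.94 relative to all genes. Hemgn, an erythroid nuclear protein, changed by -6.32 ± 0.62. All 10 megakaryocyte genes fell (10 adjusted over the list alone; camera adjusted p = 4.9e-04, adjusted p = 0.379 with an estimated correlation), among them the platelet receptor subunit Gp9 (-3.69 ± 0.42). Stem and progenitor genes fell in 8 of 11 (8 adjusted over the list alone, with camera adjusted p = 0.00508, adjusted p = 0.379 with an estimated correlation), among them the transcriptional regulators Lmo2 (-4.65 ± 0.42) and Myb (-3.23 ± 0.31). Neutrophil granule genes fell in 11 of 14 (13 adjusted over the list alone, with camera adjusted p = 0.0283, adjusted p = 0.587 with an estimated correlation), among them the protease Elane (-4.44 ± 0.77). All 23 cell cycle genes fell (23 adjusted over the list alone; camera adjusted p = 3.7e-06, adjusted p = 0.396 with an estimated correlation), among them Rrm2, a subunit of ribonucleotide reductase (-4.60 ± 0.63), and Mki67, a marker of proliferation (-4.21 ± 0.70). All 9 oncofetal genes fell (9 adjusted over the list alone; camera adjusted p = 0.0117, adjusted p = 0.379 with an estimated correlation), and Afp, the fetal plasma protein, changed by -4.67 ± 1.2 (adjusted p = 0.00304). In the imprinted growth network 10 of 12 members fell and 1 rose, a list that the camera test did not call (adjusted p = 0.081, and adjusted p = 0.591 with an estimated correlation), with the growth factor Igf2 at -4.13 ± 1.23. Dlk1, an imprinted membrane protein that also has a copy on an alternate scaffold and is therefore uncertain, changed by -6.66 ± 0.45.

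The Kupffer cell, sinusoidal endothelium and stellate cell lists held members that passed in both directions. In the Kupffer cell list 4 of 12 members rose and 1 fell, and its median of 0.31 turned to -0.02 with globins left out of the totals, while relative to all genes it was 0.79 and 0.7. Vsig4, a complement receptor of resident macrophages, changed by 3.11 ± 0.56, and C1qc, the most abundant member, by 0.27 ± 0.35 without passing the test (adjusted p = 0.513). Of the sinusoidal endothelium, 3 of 11 members rose and 4 fell, with Clec4g, an endothelial lectin, at 2.63 ± 0.42. Its median of -0.3 turned to 0.28 with quantile normalization, 0.16 with median ratios and 0.15 with the GC trend removed, which moved all genes upward, and relative to all genes it was 0.18, 0.33, 0.21 and 0.12 in that order. Of the stellate cell list 5 of 13 rose and 3 fell, with Ecm1 at 2.08 ± 0.39 and the collagen Col1a1 at -1.73 ± 0.49. Of the cholesterol synthesis list 2 of 19 rose and 4 fell, and the median of -0.37 turned to 0.16 with median ratios and 0.15 with the GC trend removed, while relative to all genes it was 0.11, 0.21 and 0.12 in that order.

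By limma-trend with Benjamini-Hochberg adjustment, 2394 of 13714 tested genes were higher and 6801 lower in the postnatal weeks. The median of all genes was -0.48, so 26% of the calls were higher. Under quantile normalization (median -0.05) 4044 genes were higher and 4517 lower, 47.2% higher. With median ratios (median -0.05) it was 4002 genes and 46.5%, and with the GC trend removed (median 0.03) 4576 higher and 4386 lower, 51.1%. No single library left out moved a count by more than 1.5 times or ended the call of a gene named above, but Afp, Igf2 and Col1a1 did not pass with W6 and W8 both left out or with all 8 postnatal libraries as the later group, and Igf2 and Col1a1 not without E13.5, E16.5 and W6. None of the 29 lists that camera called with the preset correlation was called with an estimated one, where the lowest adjusted p was 0.0853.

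The postnatal days were compared with the embryonic days to ask how the liver of the first days differs from that of the fetus. Fatty acid oxidation and ketogenesis genes rose in 17 of 20 tested and gluconeogenesis and glycogen genes in 7 of 14, with 1 lower, while erythroid genes fell in 16 of 19 and cholesterol synthesis genes in 7 of 19. With an estimated correlation these lists had adjusted p = 0.252, 0.252, 0.378 and 0.546 in that order. Apoa4, an apolipoprotein of dietary fat transport (chromosome 9, 46240844 to 46243458, identifier gene21943), rose from 2.61 ± 2.23 FPKM (n = 7 ages) to 603 ± 662 FPKM (n = 3 ages), a log2 change of 6.98 ± 0.72 (adjusted p = 4.4e-05). Pck1 rose from 4.74 ± 3.58 to 526 ± 141 FPKM (6.67 ± 0.52; adjusted p = 6.5e-06). Cyp4a14, a fatty acid omega-hydroxylase, changed by 6.71 ± 1.51, Igfbp2, an IGF-binding protein, by 6.52 ± 1.17 and Serpina3m, a serpin of the liver, by 6.49 ± 0.73. Hba-x, an embryonic globin, fell from 462 ± 814 to 1.5 ± 1.01 FPKM (-5.84 ± 1.08; adjusted p = 0.00234), and Serpina6, the corticosteroid-binding globulin, changed by -5.46 ± 1.06. The embryonic globins Hbb-y and Hbb-bh1, uncertain because of copies on an alternate scaffold, changed by -5.65 ± 1.42 and -4.91 ± 1.16.

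Fatty acid oxidation and ketogenesis rose in 17 of 20 (17 adjusted over the list alone) tested members (camera adjusted p = 2.4e-09, adjusted p = 0.252 with an estimated correlation), with a median 1.82 above that of all genes. Cpt1a, which carries fatty acids into mitochondria, changed by 3.73 ± 0.42 and the peroxisomal thiolase Acaa1b by 4.08 ± 0.75. The P450 list rose in 17 of 23 (19 adjusted over the list alone, with camera adjusted p = 3.3e-12, adjusted p = 0.236 with an estimated correlation), with Cyp2e1 at 6.35 ± 0.66 and Cyp1a2 at 5.09 ± 0.57. Plasma proteins rose in 13 of 16 (15 adjusted over the list alone, with camera adjusted p = 2.6e-08, adjusted p = 0.252 with an estimated correlation) and complement in 15 of 18 (15 adjusted over the list alone, with camera adjusted p = 1.1e-08, adjusted p = 0.252 with an estimated correlation). Amino acid catabolism rose in 13 of 18 (16 adjusted over the list alone, with camera adjusted p = 4.7e-10, adjusted p = 0.252 with an estimated correlation). Hpx, which binds free heme, changed by 3.46 ± 0.57, Mbl2 by 5.05 ± 0.80, and Agxt, which detoxifies glyoxylate, by 4.91 ± 0.60. In the gluconeogenesis list 7 of 14 rose and 1 fell, with G6pc, which releases free glucose, at 5.54 ± 0.90 and Fbp1 at 5.18 ± 1.32. Hepatocyte transcription factors rose in 8 of 18 (14 adjusted over the list alone, with camera adjusted p = 2.6e-06, adjusted p = 0.252 with an estimated correlation), among them the fatty acid receptor Ppara (2.13 ± 0.62).

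Erythroid genes fell in 16 of 19 (19 adjusted over the list alone, with camera adjusted p = 2.0e-06, adjusted p = 0.378 with an estimated correlation), among them the transcription factors Klf1 (-2.49 ± 0.57) and Tal1 (-2.29 ± 0.55), while the membrane gene Slc4a1 was at -2 ± 0.78 (adjusted p = 0.0622). Cholesterol synthesis fell in 7 of 19 (8 adjusted over the list alone, with camera adjusted p = 0.0121, adjusted p = 0.546 with an estimated correlation), with Fdps, which makes farnesyl diphosphate, at -2.22 ± 0.67. Cell cycle genes fell in 7 of 23 (12 adjusted over the list alone, with camera adjusted p = 3.5e-04, adjusted p = 0.511 with an estimated correlation), among them the replication licensing gene Mcm2 (-1.79 ± 0.60). In the lipogenesis list 4 of 14 rose and 2 fell (4 and 4 adjusted over the list alone), with the elongase Elovl5 at 2.39 ± 0.41 and the fatty acid synthase Fasn at -1.64 ± 0.56. Markers of several other cells rose instead: Kupffer cell genes rose in 5 of 12 (7 adjusted over the list alone, with camera adjusted p = 1.6e-05, adjusted p = 0.264 with an estimated correlation). B cell genes rose in 3 of 10 (3 adjusted over the list alone, with camera adjusted p = 0.00116, adjusted p = 0.415 with an estimated correlation). Cholangiocyte genes rose in 4 of 8 (4 adjusted over the list alone, with camera adjusted p = 9.8e-04, adjusted p = 0.252 with an estimated correlation), and stellate cell genes in 4 of 13 (5 adjusted over the list alone, with camera adjusted p = 0.00159, adjusted p = 0.41 with an estimated correlation). Sinusoidal endothelium genes rose in 3 of 11 (3 adjusted over the list alone, with camera adjusted p = 7.0e-04, adjusted p = 0.346 with an estimated correlation), and matrix genes in 3 of 17 (2 adjusted over the list alone, with camera adjusted p = 0.00348, adjusted p = 0.511 with an estimated correlation). T and NK cell genes rose in 2 of 3 (2 adjusted over the list alone). Vsig4 changed by 3.59 ± 0.66 and Ms4a1, the B cell antigen CD20, by 1.65 ± 0.19. Ms4a1 lay at 0.3624 FPKM (E18.5) or less before birth and passed the filter through D1, D3 and D5 alone. Its change is therefore not free of that selection. No tested neutrophil gene passed limma's test (0 adjusted over the list alone, 0 at an unadjusted p under 0.05) and no megakaryocyte gene did (0 adjusted over the list alone, 1 at an unadjusted p under 0.05), with S100a9, a calcium-binding protein of neutrophils, at 1.16 ± 1.18 (adjusted p = 0.461).

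By limma-trend, 1663 of 13714 genes were higher and 2457 lower in the postnatal days, 40.4% of the calls higher, with a median of all genes of -0.16. The share higher was 27% with globins left out of the totals (median -0.28), 55.3% with the 50 most abundant genes left out (median -0.01) and 53.2% with median ratios (median 0.03), and with the 50 genes left out 1427 genes were lower. The counts leaned on single libraries: without D3 they were 940 higher and 1080 lower, without D5 488 and 296, and without E14.5 1599 genes were lower. Of the genes named above, Ppara, Fdps, Mcm2 and Fasn lost the call without D3, and these with Fbp1, Klf1, Tal1, Hbb-y and Hbb-bh1 without D5. Mcm2 and Fasn were near the threshold: both lost the call without any 1 of E12.5, E13.5, E15.5, E16.5 and D1, and Mcm2 also without E14.5. Fdps lost it without D1 as well. Under the alternative settings, Fasn, Mcm2, Fdps and Ppara were the only genes named above to lose the call under any: Fasn under quantile normalization, median ratios, GC removal and the depth covariate, and Ppara with E14.5 to E18.5 as the embryonic group. With E14.5 to E18.5 as the embryonic group 1004 were higher and 1034 lower, and with the GC trend removed 2607 were higher. None of the 26 lists called with the preset correlation was called with an estimated one (lowest adjusted p = 0.236).

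The postnatal weeks were compared with the postnatal days to ask what changed after the first days of life. Phase II enzymes rose in 5 of 23 tested, while neutrophil granule genes fell in 11 of 14, erythroid genes in 19 of 19 and cell cycle genes in 17 of 23. With an estimated correlation these lists had adjusted p = 0.0945, 0.288, 0.288 and 0.368 in that order. Cyp2c29, a cytochrome P450 of the Cyp2c cluster with close paralogs that may share reads (chromosome 19, 39287044 to 39330713, identifier gene40813), rose from 1.38 ± 0.342 FPKM (n = 3 ages) to 462 ± 437 FPKM (n = 5 ages), a log2 change of 6.14 ± 1.29 (adjusted p = 0.00956). Tdo2 rose from 15.5 ± 14.1 to 253 ± 198 FPKM (3.82 ± 0.75; adjusted p = 0.0074). Cyp2c50 changed by 3.97 ± 0.71, Cml2 by 3.81 ± 0.93 and Cyp2d13 by 3.66 ± 0.56. Camp, the cathelicidin peptide of neutrophil granules (chromosome 9, 109847377 to 109849456, identifier gene23050), fell from 392 ± 158 to 40.0 ± 82.7 FPKM (-5.69 ± 1.36; adjusted p = 0.0185). The stefins Stfa1, Stfa2 and Stfa3, cysteine protease inhibitors and close paralogs of each other, changed by -6.04 ± 1.37, -5.49 ± 1.40 and -5.60 ± 1.36.

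Neutrophil granule genes fell in 11 of 14 (14 adjusted over the list alone, with camera adjusted p = 1.7e-06, adjusted p = 0.288 with an estimated correlation), with S100a8 at -5.06 ± 1.19 and Ngp at -5.37 ± 1.38. All 19 tested erythroid genes fell (19 adjusted over the list alone; camera adjusted p = 1.0e-13, adjusted p = 0.288 with an estimated correlation), with Slc4a1 at -4.77 ± 0.83. All 10 megakaryocyte genes fell (10 adjusted over the list alone; camera adjusted p = 5.6e-07, adjusted p = 0.288 with an estimated correlation), with Gp9 at -2.65 ± 0.53. Cell cycle genes fell in 17 of 23 (22 adjusted over the list alone, with camera adjusted p = 7.2e-07, adjusted p = 0.368 with an estimated correlation), among them Rrm2 (-3.03 ± 0.78) and Birc5, a regulator of chromosome segregation (-2.86 ± 0.86). Oncofetal genes fell in 3 of 9 (6 adjusted over the list alone, with camera adjusted p = 0.02, adjusted p = 0.38 with an estimated correlation), with Afp at -5.36 ± 1.5 and Cd24a at -4.57 ± 0.84. The imprinted growth network fell in 6 of 12 (9 adjusted over the list alone, with camera adjusted p = 0.00245, adjusted p = 0.38 with an estimated correlation), with Igf2 at -5.14 ± 1.54. B cell genes fell in 4 of 10 (8 adjusted over the list alone, with camera adjusted p = 9.4e-04, adjusted p = 0.377 with an estimated correlation), with Ms4a1 at -1.32 ± 0.20 and Cd79b, a part of the B cell receptor, at -2.82 ± 0.64. Ms4a1 passed the filter through the postnatal days alone, so its fall is not free of that selection. Matrix genes fell in 4 of 17 (12 adjusted over the list alone, with camera adjusted p = 0.00166, adjusted p = 0.449 with an estimated correlation), led by the matrix glycoprotein Thbs1 (-2.81 ± 0.53). Other lists of non-hepatocyte cells had negative medians as well. These were -1.06 for stem and progenitor, -0.91 for sinusoidal endothelium, -1.26 for mesothelium, -0.69 for Kupffer cell and -0.42 for stellate cell genes.

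Phase II enzymes rose in 5 of 23 (10 adjusted over the list alone, with camera adjusted p = 2.1e-15, adjusted p = 0.0945 with an estimated correlation), among them Ugt2a3 (2.44 ± 0.60) and Gstm1, a glutathione transferase (2.10 ± 0.58). The P450 list rose in 3 of 23 (3 adjusted over the list alone, with camera adjusted p = 8.4e-09, adjusted p = 0.288 with an estimated correlation), with Cyp1a2 at 2.13 ± 0.60, while Cyp2e1 was at 1.02 ± 0.70 (adjusted p = 0.314). Igf1, the circulating growth factor that growth hormone induces, changed by 2.04 ± 0.52. No member of the plasma protein, coagulation or urea cycle lists passed limma's test (1, 0 and 2 at an unadjusted p under 0.05, and 0 in each adjusted over the list alone). Relative to all genes the medians of these lists were 0.41, 0.44 and 1.13. Their most abundant members with an estimate at every age were at -0.23 ± 0.63 for Apoa1, 0.54 ± 0.88 for Fgb and 1.22 ± 0.92 for Ass1.

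By limma-trend, 161 of 13714 genes were higher and 1462 lower, 9.9% of the calls higher, with a median of all genes of -0.33. The share higher was 44.8% under quantile normalization (623 higher, 769 lower, median 0.06), 35.8% with the GC trend removed (452 and 809, median 0.02) and 24.1% with median ratios (352 higher, median -0.09). This comparison rested on single libraries: no gene was higher and 1 was lower without D1 (325 higher at an unadjusted p under 0.05), and no gene passed either way without D3 (370 higher and 2723 lower unadjusted). Every gene named above that was tested in those fits lost the call without D1 and without D3, 24 of 24 each time. Of the 25 called genes named above, 11 lost it without W6, 11 without W8 and 8 without W3, and 6 of 24 without D5. Birc5 and Igf2 also lost it without any 1 library from E13.5 to E17.5, with median ratios and with the GC trend removed, and Igf2 under quantile normalization. With no filter 9 of the 25 lost it, and without E13.5, E16.5 and W6 17 did. Higher genes numbered 383 without W1, 298 without W2, 80 without W3, 63 without W6 and 74 without W8. Lower genes numbered 2959 without W1, 799 without W3, 581 without W6 and 577 without W8. Without both W6 and W8, which were left out after the data had been seen, 3 genes were higher and 18 lower. None of the 29 lists called with the preset correlation was called with an estimated one (lowest adjusted p = 0.0945).

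The slope over the 7 embryonic days asked which genes changed steadily before birth. Plasma protein genes rose in 16 of 16 tested, neutrophil granule genes in 13 of 14, Kupffer cell genes in 11 of 11 and B cell genes in 8 of 8, while cell cycle genes fell in 18 of 23. With an estimated correlation these lists had adjusted p = 0.0371, 0.0497, 0.0371, 0.0915 and 0.479 in that order. Ahsg, a plasma glycoprotein (chromosome 16, 22892015 to 22899451, identifier gene35957), rose from 376 FPKM at E12.5 to 18260 FPKM at E18.5, a log2 slope of 1.00 ± 0.05 per day (SE, n = 7 ages; adjusted p = 8.3e-06). Aqp8, a water channel, had a slope of 1.30 ± 0.14, Tff3, a trefoil peptide, of 1.30 ± 0.06, Fbp1 of 1.29 ± 0.18, Adh1, an alcohol dehydrogenase, of 1.23 ± 0.13 and Uox, the urate oxidase, of 1.23 ± 0.11. Hba-x fell from 2246 to 19 FPKM (-1.08 ± 0.09 per day; adjusted p = 8.9e-05), and the growth factor Mdk had a slope of -0.67 ± 0.06. Hbb-y and Hbb-bh1, uncertain as above, had slopes of -1.47 ± 0.07 and -1.22 ± 0.03, and Cited1, a transcriptional co-regulator, of -0.68 ± 0.15.

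All 16 tested plasma protein genes rose (16 adjusted over the list alone; camera adjusted p = 1.1e-16, adjusted p = 0.0371 with an estimated correlation), as did all 16 coagulation genes (16 adjusted over the list alone; camera adjusted p = 1.9e-18, adjusted p = 0.0371 with an estimated correlation). All 18 complement genes rose as well (18 adjusted over the list alone; camera adjusted p = 1.1e-16, adjusted p = 0.0377 with an estimated correlation). Apoh, a lipid-binding plasma protein, had a slope of 0.99 ± 0.05 per day, the fibrinogen chain Fga of 0.82 ± 0.04 and C8b of 0.80 ± 0.05. Amino acid catabolism rose in 15 of 17 (16 adjusted over the list alone, with camera adjusted p = 8.0e-15, adjusted p = 0.0371 with an estimated correlation), with Hpd, a tyrosine catabolic enzyme, at 0.90 ± 0.04. The urea cycle rose in 9 of 10 (9 adjusted over the list alone, with camera adjusted p = 2.9e-08, adjusted p = 0.0407 with an estimated correlation), with Arg1 at 1.07 ± 0.07. Neutrophil granule genes rose in 13 of 14 (13 adjusted over the list alone, with camera adjusted p = 2.3e-11, adjusted p = 0.0497 with an estimated correlation), with S100a9 at 0.86 ± 0.09 and Camp at 0.86 ± 0.09. All 11 tested Kupffer cell genes rose (11 adjusted over the list alone; camera adjusted p = 9.5e-11, adjusted p = 0.0371 with an estimated correlation), with the lectin Clec4f at 0.85 ± 0.06. All 8 B cell genes rose (8 adjusted over the list alone; camera adjusted p = 1.6e-09, adjusted p = 0.0915 with an estimated correlation), with Vpreb1, a part of the pre-B cell receptor, at 0.92 ± 0.09. Cell cycle genes fell in 18 of 23 (21 adjusted over the list alone, with camera adjusted p = 9.2e-04, adjusted p = 0.479 with an estimated correlation), with Mcm5 at -0.34 ± 0.06. Stem and progenitor genes, a list that camera did not call, fell in 8 of 11 (8 adjusted over the list alone, with camera adjusted p = 0.0697, adjusted p = 0.281 with an estimated correlation), with the surface protein Cd34 at -0.32 ± 0.04. In the pericentral list 1 of 7 rose and 3 fell, with the ammonia transporter Rhbg at -0.51 ± 0.08.

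By limma-trend, 1797 of 12615 genes rose and 4624 fell per day, 28% of the calls rising, with a median slope of all genes of -0.07. The share rising was 61% with median ratios (1608 falling), 53.9% with the GC trend removed (2947 rising, 2522 falling), 46.8% with the 50 most abundant genes left out (2526 falling) and 41% under quantile normalization (3004 falling). Without E18.5 the falling genes numbered 2671, and with E15.5 to E17.5 left out, a choice made after the data had been seen, 1091 rose and 2539 fell. Of the 23 lists called with the preset correlation, 14 were called with an estimated one.

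The slope per doubling of age over the postnatal weeks, from 5 libraries, asked which genes rose or fell with age from W1 to W8. Such a slope does not tell a steady change from a step between adjacent ages. Acute phase genes rose in 6 of 14 tested and male-biased genes in 4 of 6, while imprinted growth genes fell in 9 of 10, cell cycle genes in 20 of 20 and matrix genes in 14 of 16. With an estimated correlation the matrix list had adjusted p = 0.322 and the others adjusted p = 0.305. H19, an imprinted non-coding RNA (chromosome 7, 142575532 to 142578146, identifier gene19032), fell from 5891 FPKM at W1 to 15.9 FPKM at W8, a log2 slope of -3.20 ± 0.33 per doubling (SE, n = 5 ages; adjusted p = 0.00631). Igf2, its imprinted neighbour, had a slope of -3.10 ± 0.55 and Afp of -2.95 ± 0.54. The major urinary protein genes Mup10, Mup11, Mup14 and Mup15, pheromone carriers whose near-identical copies may share reads, had slopes of 4.14 ± 0.88, 4.2 ± 0.83, 4.2 ± 0.84 and 4.16 ± 0.83. Cyp4a14 had a slope of -2.70 ± 0.58 and the female-biased Cyp2b9 of -2.68 ± 0.54.

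All 20 tested cell cycle genes fell (20 adjusted over the list alone, with camera adjusted p = 3.9e-12, adjusted p = 0.305 with an estimated correlation), with Birc5 at -1.76 ± 0.20 and Ccnb2, a mitotic cyclin, at -1.60 ± 0.15. Blood cell lists had negative median slopes too. These were -0.9 for erythroid (6 tested), -0.97 for megakaryocyte (4), -1.36 for neutrophil granule (8) and -0.82 for B cell genes (3). The imprinted growth network fell in 9 of 10 (9 adjusted over the list alone, with camera adjusted p = 4.7e-06, adjusted p = 0.305 with an estimated correlation), with Cdkn1c, an inhibitor of the cell cycle, at -2.16 ± 0.15. Matrix genes fell in 14 of 16 (15 adjusted over the list alone, with camera adjusted p = 2.3e-07, adjusted p = 0.322 with an estimated correlation), with the basement membrane gene Nid1 at -1.37 ± 0.16. Stellate cell genes fell in 8 of 13 (11 adjusted over the list alone, with camera adjusted p = 4.4e-04, adjusted p = 0.447 with an estimated correlation), with Col3a1 at -1.11 ± 0.19. Sinusoidal endothelium genes fell in 6 of 11 (10 adjusted over the list alone, with camera adjusted p = 0.00174, adjusted p = 0.366 with an estimated correlation), with the scavenger receptor Stab2 at -0.61 ± 0.11. Acute phase genes rose in 6 of 14 (8 adjusted over the list alone, with camera adjusted p = 4.4e-14, adjusted p = 0.305 with an estimated correlation), with Orm1 at 3.90 ± 0.43 and Saa1, which shares near-identical sequence with Saa2, at 3.68 ± 0.50. Male-biased genes rose in 4 of 6 (5 adjusted over the list alone, with camera adjusted p = 6.6e-09, adjusted p = 0.305 with an estimated correlation), with the steroid hydroxylase Cyp7b1 at 2.72 ± 0.40. Female-biased genes fell in 3 of 8 (4 adjusted over the list alone, with camera adjusted p = 0.0472, adjusted p = 0.487 with an estimated correlation), with Hao2, a hydroxyacid oxidase, at -2.17 ± 0.44. Phase II enzymes rose in 7 of 23 (8 adjusted over the list alone, with camera adjusted p = 1.3e-07, adjusted p = 0.305 with an estimated correlation), with the methyltransferase Nnmt at 2.53 ± 0.56. Of the lipogenesis list 3 of 13 rose (3 rose and 1 fell adjusted over the list alone), with the desaturase Scd1 at 2.64 ± 0.34.

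The mean log2(FPKM + 1) of the male-biased list was 2.5, 2.28, 2.47, 8.04 and 7.84 at W1, W2, W3, W6 and W8. At the same ages that of the female-biased list was 3.94, 3.91, 4.19, 0.86 and 0.62. The sex-biased lists thus changed in a step between W3 and W6 rather than steadily. The acute phase list was at 5.63, 5.46, 7.64, 8.28 and 10.92, and the erythroid list at 4.05 at W1 and 1.45 at W2. Saa1, an acute phase apolipoprotein, was at 3494 FPKM at W6 and 33180 FPKM at W8, and Lcn2, an iron-siderophore binding protein, at 39.9 and 2375 FPKM. The cholesterol synthesis list stood at 3.77 at W2 and 6.98 at W3.

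By limma-trend, 179 of 11458 genes rose and 1658 fell, 9.7% of the calls rising, with a median slope of -0.18. The share rising was 33.5% under quantile normalization (330 falling), 30.7% with the GC trend removed (276 rising, 624 falling) and 23.8% with median ratios (787 falling). Without W8 no gene passed (366 rising and 2668 falling at an unadjusted p under 0.05), and none passed with log2 depth as a covariate (306 and 2176 unadjusted) or without the filter on low values (625 and 5932 unadjusted). Of the genes named above, Igf2, Afp, Stab2 and Nnmt lost the call without W1 and Mup10 without W2. Without W6 14 of the 22 lost it, and under quantile normalization Afp, Mup10, Cyp4a14, Stab2, Hao2 and Nnmt did. Rising genes numbered 79 without W1, 115 without W2 and 29 without W6. Falling genes numbered 218 without W1, 541 without W2, 553 without W3 and 402 without W6. None of the 23 lists called with the preset correlation was called with an estimated one (lowest adjusted p = 0.305).

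**Figure D3:**
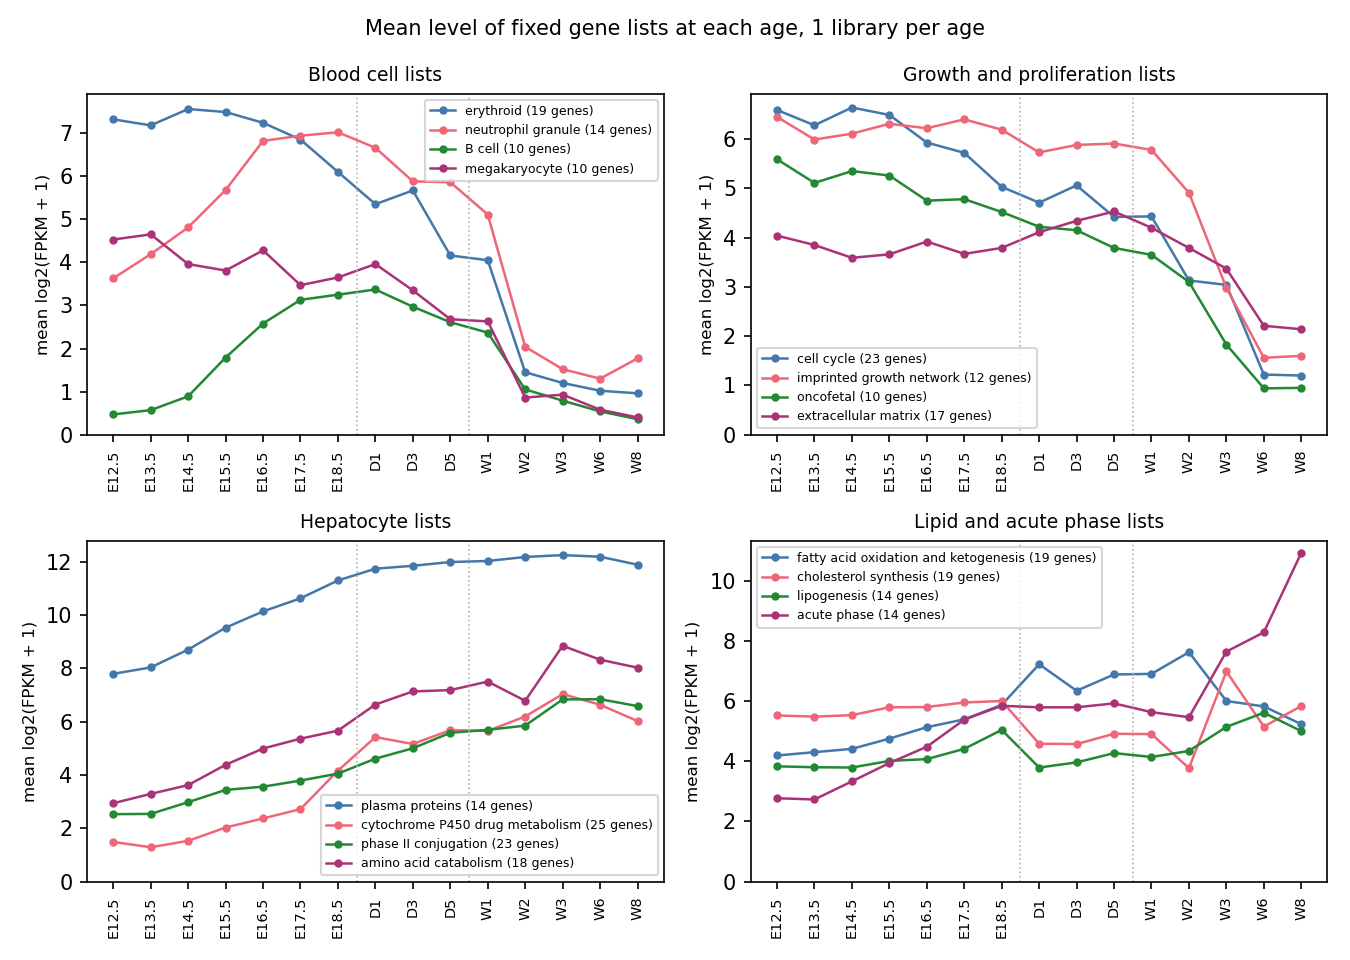
Mean log2(FPKM + 1) of fixed gene lists (y axis) in each of the 15 libraries in order of age (x axis), 1 line per list and 1 point per library. The erythroid list runs from 7.32 at E12.5 to 0.96 at W8, and the P450 list from 1.49 to 6.02.

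Genes highest in the postnatal days, the search for a peak around birth, were those past the threshold against both other periods. Antibody genes led this set: 33 of its 83 genes were immunoglobulin genes, against 55 among the 13714 tested (odds ratio 403, Fisher's exact test, two-sided p = 4.8e-62, chosen after the values were seen, with genes that are not independent). The filter asked for over 1 FPKM in 3 libraries, as many as the postnatal days hold. Low genes could thus enter the test by being high in those days alone, so these values are not free of that selection. With the filter on 5 libraries the set held 48 genes. Ighm, the heavy chain of IgM, which also has a copy on an alternate scaffold, was at 7.13 ± 6.84, 30.4 ± 10.6 and 4.56 ± 4.42 FPKM in the embryonic days, postnatal days and postnatal weeks. Of the B cell list 3 members were in the set, among them Ms4a1 and Cd22, which restrains the B cell receptor. Cyp3a41a, a cytochrome P450 of the female-biased list with close paralogs, was at 2.44 ± 5.73, 82.5 ± 10.3 and 26.1 ± 51.2 FPKM. Pld4, an endosomal nuclease of immune cells, was at 9.40 ± 3.67, 18.4 ± 2.86 and 8.11 ± 3.20 FPKM and Cd97, an adhesion receptor, at 11 ± 3.48, 20.8 ± 1.47 and 10.5 ± 3.78 FPKM, and no other gene of the set reached a mean of 10 FPKM. By limma-trend 83 genes peaked and 0 were lowest in the postnatal days (17 at an unadjusted p under 0.05 in both). Independent lists of the same sizes would share 177 genes, more than the 83, and 20 simulations with no effect gave at most 1. The simulations shared the postnatal days between both comparisons, as the data did, but drew genes independently and without change with age. The excess over them therefore does not tell a peak apart from other change with age. No gene passed without D1 (201 unadjusted) or without D3 (169 unadjusted). The count was 34 without D5, 130 without E18.5, 181 without W1, 126 without W2, 54 without W3, 46 without W6 and 47 without W8.

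E18.5 and D1, with 1 library each, were set side by side to describe the step across birth, with no replicate check and no test. Apoa4 was at 7.04 FPKM at E18.5 and 1364 FPKM at D1, and Pck1 at 11.9 and 424 FPKM. Sult2a1, a sulfotransferase, was at 2.02 and 77.6 FPKM, Cyp4a14 at 39.7 and 804 FPKM, and Hamp, the iron hormone hepcidin, at 148 and 2065 FPKM. Lower at D1 were A2m, a protease inhibitor (372 and 14.3 FPKM), Scd1 (74.6 and 3.04 FPKM) and Aqp8 (279 and 17.0 FPKM). All 20 members of the fatty acid oxidation list were higher at D1, with a median log2 ratio of 1.16 above 100% of 10000 random lists matched on mean expression. The P450 list had a median of 0.97 (21 of 24 higher), amino acid catabolism of 0.86 (16 of 18) and the pericentral list of 0.84 (9 of 9), each above 100% of the random lists. The female-biased list had a median of 0.66 (6 of 10), phase II of 0.61 (16 of 20) and plasma proteins of 0.57 (10 of 14). All 19 cholesterol synthesis genes were lower, with a median of -1.27, and 10 of 14 lipogenesis genes, with a median of -1.29, each above 0% of the random lists. Globins had a median of -1.30 (0 of 7 higher), erythroid genes of -0.73 (0 of 19) and immediate early genes of -0.28 (1 of 11). Cell cycle genes had a median of -0.29 (1 of 23 higher), neutrophil genes of -0.2 (4 of 14) and stellate cell genes of 0.35 (11 of 12). The circadian clock list (0.41) and the sex chromosome list (0.88) lay above 99.7% and 99.4% of random lists. Random lists hold unrelated genes, so lists whose genes vary together reach the tails easily. These ranks thus do not tie a list to birth, and time of day and sex were not separated from it. Small nuclear and nucleolar RNAs such as Rnu2-10 and Snora78 were among the largest differences, and FPKM of such short transcripts is unstable.

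**Figure D4:**
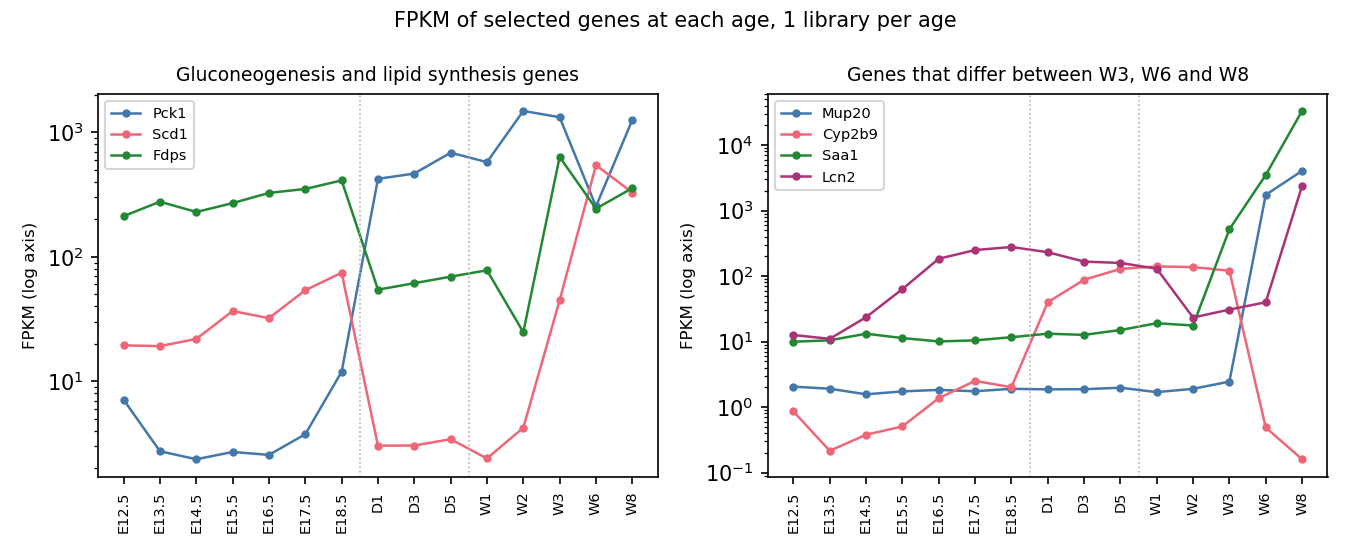
FPKM of Pck1, Scd1 and Fdps (left) and of Mup20, Cyp2b9, Saa1 and Lcn2 (right), chosen after the values were seen (y axis, log scale; x axis, the 15 libraries in order of age; 1 point per library). Pck1 lies at 11.9 FPKM at E18.5 and 424 FPKM at D1, and Saa1 at 3494 FPKM at W6 and 33180 FPKM at W8.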

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

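In groups of 5 or 7 libraries, the highest or lowest library was set apart when its gap to the next exceeded the limit of Dixon's test. Of 327 groups of values 39 passed, while chance passes about 1 in 20 groups of values without a trend. These groups are ordered ages, and steep change with age can set apart an end age such as E18.5 or W1. A pass therefore does not mark a library as faulty. The genes tested are those named here, many chosen for large changes, and groups that share genes are not independent. The tests of explanations below were chosen after the results they measure were seen.

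W1 stood above the other postnatal weeks in blood lists, as mean log2(FPKM + 1): erythroid 4.05 (others 0.96 to 1.45), megakaryocyte 2.63 (0.4 to 0.93) and neutrophil granule 5.11 (1.3 to 2.04). Among genes the W1 values in FPKM were Slc4a1 93.82, Rhd 29.14, Hemgn 28.3, Elane 23.08, Vpreb1 8.403, Tal1 8.063, Gp9 7.837, A2m 5.342 and Myb 2.211, each the highest of the 5 weeks, while Cyp2d13 was lowest at W1 (6.565). At W2 the globin list stood at 2.24 (0.82 to 1.17), with Hbb-y at 21.54 FPKM. This level covers only the 4 members with an estimate at every age, Hba-x, Hbb-bh1, Hbb-bh2 and Hbb-y. The share of globins and Alas2 in the summed FPKM was 4.4% at W1 and 0.9% at W2. Also at W2, Apoa4 was at 987.9 FPKM (92.32 to 150.7) and Rnu2-10 was listed at 0 (33.85 to 99.82). At W6 the relative depth was 1.186 (0.96 to 1.006), Serpina3m was lowest at 94 FPKM and Snora78 was at 1110 FPKM with the other weeks listed at 0.

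E18.5 stood apart from the earlier embryonic days in the growth hormone and IGF list, 5.25 (others 2.98 to 3.83), and in the male-biased list, 2.68 (1.26 to 1.82). Highest at E18.5 in FPKM were Apoc3 348.1, Cyp2e1 89.77 (4.309 to 13.02), Ugt1a1 69.38, G6pc 64.02, Cyp4a14 39.65, Elovl5 32.49, Serpina3m 30.84, Cpt1a 26.94, Cyp3a41a 15.42, Nr1i3 14.36, Tat 9.499, Ugt2a3 0.9984 and Ms4a1 0.3624. Lowest there were Dlk1 (103.8) and Serpina6 (17.57, others 556.3 to 1605). At E13.5 Igf1 was lowest (1.808) and Snora78 was at 906.5 FPKM with the other embryonic days listed at 0. Entries on scaffolds outside the chromosomes, which no comparison used, took up to 4.7% of the FPKM (W8), against 1.4% at W1.

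E13.5, E16.5 and W6 departed from the mean of their adjacent ages along transcript GC content, with a smallest rho of 0.451 among the 3, while E14.5, E15.5 and E17.5, beside them, had -0.611, -0.541 and -0.459, as follows where an adjacent library is shifted. The 3 libraries were singled out by these same values. For length, a rho over 0.3 in size in each of the 3 libraries was set as the bound for a length bias and one under 0.15 in all 3 as the bound against it. The largest in size was -0.236, between these bounds, which leaves length open, and, in a test chosen after that value was seen, -0.107 given GC, which argues against length apart from GC. Fewer dividing cells at E13.5 and E16.5 would lower cell cycle genes below genes of the same GC content. The median of the 23 cell cycle genes lay at -0.01 from such genes at E13.5 (bootstrap range -0.14 to 0.03) and at 0.07 at E16.5 (-0.01 to 0.18). Members went both ways (SD 0.6 and 0.56), so fewer dividing cells cannot be told apart from other causes. A GC bias of the libraries may thus account for part of these departures, no sequencing batch is given to test it against, and change with age stays open as untested.

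Hepatocyte lists were higher in the postnatal weeks than in the embryonic days, over which blood RNA took a falling share. A smaller share of blood cell RNA would raise every hepatocyte gene alike, yet the P450 list rose by 2.28 more than the plasma protein list (medians 4.5 and 2.22, bootstrap range over genes 1.3 to 3.31). Leaving globins and Alas2 out of the totals moved the median of all genes from -0.48 to -0.72, a small shift beside the P450 median of 4.5. That 22 of 23 tested P450 genes still passed upward was bound to follow from a shift of this size. The listed globin share of the totals is thus too small to give the P450 rise, and this says nothing about other blood cell RNA. Change in expression within hepatocytes with age may contribute, as a hypothesis, and a change in the mix of other cells was not excluded. Animal sex changed together with period by Xist and Y-linked RNA, so it cannot be told apart from period in this comparison.

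Acute phase genes were higher at W8 than at W6, 1 library each, with a median log2 ratio of 2.24 and 14 of 14 higher. With the GC trend removed the median was 2.05, so a GC difference between these libraries does not account for it. The neutrophil list had a median ratio of 0.75 (7 genes, SD 0.95), between the bounds set for the test, so a contribution of neutrophil RNA to the list cannot be told apart from other causes. In a test chosen after that value was seen, the 4 most abundant neutrophil genes summed to 0.0248 times the Lcn2 level at W8, against 14.2 to 35.6 times it from E12.5 to W1, 4.89 at W2, 1.46 at W3 and 0.509 at W6, so neutrophil RNA of the makeup from E12.5 to W1 would not bring the Lcn2 level of W8. An acute phase response in the animal or animals of W8 may be a candidate explanation, and with 1 library it could not be separated from sampling of that animal.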

How the results depend on the processing

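The alternatives with the median ratio, the GC trend removed, and E13.5, E16.5 and W6, or E15.5 to E17.5, or W6 and W8 left out were chosen after seeing the data; the others and the random splits were planned. Count-based alternatives planned for raw counts (other size factors, another count test, count filters) were not run, since the tables hold FPKM. No paired analysis was possible because each age has 1 library and replicate numbers mark ages. Among the named genes, 127 of 135 results passed, and none of these changed sign under an alternative; of 3283 values, 2953 kept direction and call, 320 lost the call, 5 gained it and 5 changed sign. The sign changed in 3 results that had not passed: C1qc in weeks against embryonic days (0.268) with globins out of the totals (-0.068) and with E14.5 to E18.5 (-0.081), Apoa1 in weeks against days (-0.232) with the median ratio (0.091) and GC removal (0.115), and the Lcn2 slope of the weeks (0.986) without W8 (-0.584; 2.616 without W1). Where counts moved, the cause was not tested, except that a stricter threshold leaves fewer calls by construction. Depth limits values near the floor of 0.145 to 0.191 FPKM.

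For weeks against embryonic days (2394 higher, 6801 lower) quantile normalization gave 4044 and 4517, the median ratio 4002 higher, GC removal 4576 and 4386, and a 2-fold threshold 1437 and 3763. For days against embryonic days (1663, 2457), GC removal gave 2607 higher, E14.5 to E18.5 as the embryonic group 1004 and 1034, the 2-fold threshold 1069 and 1105, and fewer were lower without the 50 most abundant genes in the totals (1427), without E13.5, E16.5 and W6 (1613) and without E15.5 to E17.5 (1523). For weeks against days (161, 1462) quantile normalization gave 623 and 769, GC removal 452 and 809, the median ratio 352 higher, no filter 98 higher, totals without globins 2249 lower, leaving out E13.5, E16.5 and W6 27 and 340, E15.5 to E17.5 55 and 645, and W6 and W8 3 and 18. For the embryonic slope (1797 rising, 4624 falling) GC removal gave 2947 and 2522, leaving out E15.5 to E17.5 1091 and 2539, a slope of at least 0.2 1197 and 1557, and fewer fell without the 50 most abundant genes (2526), under quantile normalization (3004) and with the median ratio (1608). For the slope of the weeks (179, 1658) no filter gave 0 and 0 (limma, unadjusted 625 and 5932), depth as a covariate 0 and 0 (unadjusted 306 and 2176), a filter on 5 libraries 111 and 825, GC removal 276 and 624, leaving out E13.5, E16.5 and W6 29 and 402, and the falling genes were 2671 without globins, 3681 without the 50 most abundant, 330 under quantile normalization and 787 with the median ratio. The 83 peak genes became 188 with no filter, 48 with the filter on 5 libraries, 46 with a pseudocount of 0.1, 51 with E14.5 to E18.5, 28 without E13.5, E16.5 and W6, 41 without E15.5 to E17.5, 15 without W6 and W8 and 53 with the 2-fold threshold. Other alternatives kept these counts within 1.5 times.

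With each library left out in turn, weeks against embryonic days gave 2120 to 2478 higher and 6247 to 7052 lower, and days against embryonic days 488 (without D5) to 2098 and 296 (without D5) to 3622. Weeks against days gave 0 (without D1 or D3; limma, unadjusted 325 and 370) to 383 and 0 (without D3; unadjusted 2723) to 2959. The embryonic slope gave 1303 to 1705 and 2671 to 4851, the slope of the weeks 0 (without W8; limma, unadjusted 366) to 124 and 0 (unadjusted 2668) to 553, and the peak 0 (without D1 or D3; limma, unadjusted 201 and 169) to 181. Lists called by camera went from 29 to 0, 26 to 0, 29 to 0, 23 to 14 and 23 to 0 in the order above with an estimated correlation. With a pseudocount of 0.1 the birth step lists in the upper 2.5% of random lists numbered 17 (main 15) and those in the lower 2.5% numbered 9 (main 9).

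Splits of the libraries into groups of the same sizes, 100 each with the real one, called as many genes in 1 split for weeks against embryonic days (9195, highest other 8439), 3 for days against embryonic days (4120, 5583), 3 for weeks against days (1623, 6243) and 2 for the peak (83, 704). These ranks bear only on groups drawn without regard to age, since these splits mix the ages, and they do not exclude chance. Splits that called several times the real count in the last 2 point to a structure of the samples. In a test chosen after these values were seen, groups of the same sizes were cut as runs of consecutive ages in the 5 other orders of the sizes. As many genes were called in 1 of 5 orders for weeks against embryonic days (highest 9240), 4 for days against embryonic days (9602), 5 for weeks against days (9926) and 5 for the peak (2886). None of the 4 counts thus singles out these periods among runs of ages.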

Other observations

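All values here were picked out after they had been seen. Exocrine pancreas genes were at their highest at D1 for Ctrb1 (7.76 FPKM, next 1.23 FPKM at E15.5) and Cela3b (0.839 FPKM). Tff3, kept in the intestine list, was at 4.32 FPKM at E12.5, 878 FPKM at E18.5 and 24.0 FPKM at W2. Mylpf, a myosin light chain of skeletal muscle, was at 26.0 FPKM at E12.5 and 1.21 FPKM at W8.

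Dbp, a clock output gene, was at 20.6 FPKM at W2 and 0.129 FPKM at W8, and Nr1d1 at 21.5 FPKM at W6 and 5.69 FPKM at W8. The time of day of sampling was not given in the sources used here. Hamp was at 26.8 FPKM at W1 and 7781 FPKM at W3. Among sex-biased genes, Mup20 was at 2.45 FPKM at W3, 1738 FPKM at W6 and 4034 FPKM at W8, with a copy on an alternate scaffold, and Cyp2b9 at 121, 0.489 and 0.160 FPKM at the same ages. Sult3a1 was at 3.03 FPKM at E18.5, 0.192 FPKM at D1, 0.0544 FPKM at E15.5 and listed at 0 at the other ages.

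The nuclear genes of the mitochondrial respiratory chain stood between 7.31 (W8) and 8.07 (W3) as mean log2(FPKM + 1), T and NK cell genes between 0.24 (E12.5) and 1.3 (D5), and mesothelium genes between 0.11 (W8) and 1.78 (D3).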
